A study of Rattus norvegicus with 6 samples.

How the data were processed

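The labels describe 6 samples of rat RNA, each hybridised to 1 one-colour array after RNA from 3 FAO cultures or 6 animals had been pooled. Groups were taken from the sample titles and treatments: FAO cells untreated or with deferoxamine, and liver and kidney of rats on an iron-sufficient or iron-free diet. All 6 arrays share 1 slide, so slide does not separate the groups. Per the file headers, the authors scanned the arrays and extracted spot intensities with Agilent Feature Extraction 10.7.3.1 for array design 028279, whose header names the rn4 build. The deposited intensity used here, gProcessedSignal, is background-subtracted signal on a linear scale, per the file headers, and the flags of the same files mark spots as outliers, saturated or well above background. The authors' deposited series table holds an intensity and a log2 value per probe and array. Checked against the scanner files, its intensity was within a relative tolerance of 0.0001 of the geometric mean of the probe's spots for 97.1% to 98.3% of probes, and its log2 value departed by at most 0.000405 from log2 intensity minus the array's 75th percentile. The medians of the authors' log2 columns were -3.44 and -3.31 for liver, -3.33 and -3.28 for kidney and -4.16 and -4.19 for FAO cells, control first. The table's column names stand on the same line as a comment, so columns were matched by their order and by this comparison.

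From the scanner files, log2(gProcessedSignal) of the 58717 gene spots per array was averaged over the spots of each of 30367 probes, leaving out spots flagged as outliers (680 to 1215 per array). There were 13137 probes with 1 spot, 15840 with 2 and 1390 with 10. Since less than 50% of probes were well above background on each array, every array was scaled to the 75th percentile of the 9094 probes (29.9%) well above background on all arrays. A probe counted as well above background on an array only if all of its spots did. Where 1 array of a comparison was not, the difference is a bound, bright value against the higher of the dim array's lowest detected signal and the probe's own signal, written as at least N-fold, and list medians take such genes at their bound. A Python pipeline (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6) computed all values, and normexp background correction ran in limma 3.58.1 under R 4.3.3.

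Probes were assigned to genes by the gene ID in the authors' table: 24272 probes had one and 6095 had none and were left out of gene counts. Of 19958 genes, 19142 had their ID in the RefSeq gene table of assembly GRCr8, which was used for current symbols only (3525 changed), and no coordinates are given because the array files name another build. For 3837 genes with several probes, the probe with the highest mean over the 6 arrays stands for the gene. Among genes with several measured probes, 1 of 1714 in FAO cells, 3 of 1378 in liver and 1 of 1122 in kidney had probes called in opposite directions, and 211, 179 and 91 had some probes called and others not.

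A gene was called when its difference or bound was at least 2-fold (log2 1). With 1 array per group no p-value was computed. The spot standard error comes from the spread between spots of a probe, pooled in 20 bins of signal per array, and says nothing about animals or cultures. Array number and signal over background limit the precision. The scanner's own median coefficient of variation between repeated gene spots was 21.0% on control liver, 10.9% on control kidney, 10.6% on deferoxamine FAO, 8.69% on iron-free kidney, 6.71% on iron-free liver and 6.69% on untreated FAO, and it lay outside the range the software accepts on all but the last 2.

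Before the data were examined, the comparisons, the size rule, 34 gene lists and the rule for named genes were fixed. That rule takes, per comparison, the 8 largest measured increases and decreases with a bright array, 6 genes in every case (Tfrc, Slc40a1, Fth1, Ftl1, Hamp, Rgn), up to 2 called members of each list with at least 5 measured genes, up to 3 bounds per direction, up to 10 genes called in the same direction in all comparisons and up to 6 called in opposite directions in liver and kidney. Other list members given as examples were chosen after their values were seen. Each list median was placed among 10000 random lists of the same size matched in 10 bins of signal. Overlaps are given beside the product of the list sizes over the genes measured in both.

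The steps were tested on simulated data with spot noise of these arrays: 100 genes changed 3-fold were called in the right direction in 100%, 100% and 99% of cases for FAO cells, liver and kidney, in steps of 10155, 8650 and 8251 genes, and of 100 genes changed 1.5-fold 6%, 8% and 6% were called. The changed genes were drawn only from genes far above the lowest detected signal of the control array. These shares therefore do not describe genes near background or calls made as bounds. In every simulated pair only probes well above background on the control array could be measured. Higher calls against a dim control thus had no simulated counterpart. Noise was drawn at each array's spot spread pooled by signal, which spreads a local dim patch over all probes. Alternatives fixed beforehand were quantile scaling, scaling to the median of detected probes, loess centring, the authors' table, detection on both arrays or no detection filter, a brightness filter, keeping outlier spots, the mean over probes, 1.5-fold and 3-fold rules, and a rule of 2-fold and over 3 spot standard errors. For that last rule the spread came from a probe's own spots where it had 2 or more, and was pooled only otherwise. Added after seeing the data were normexp on the median signal (offset 50), the 75th percentile over all probes, leaving out spots in noisy blocks, and only probes with at least 2 spots that do not overlap between arrays. A block of 16 by 16 spots was noisy when spots of the 10-spot probes departed from their probe's median by a root mean square above 0.5 on the log2 scale. The planned normexp correction of mean signals was not run because the scanner files used here hold no mean signal column.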

Results

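RNA was measured on 6 one-colour rat expression arrays, all on 1 slide, to compare iron deprivation in a cultured liver cell line and in rats. FAO cells, a rat liver cell line, were left untreated or given 100 µM of deferoxamine, an iron chelator, for 24 h. Rats of the Wistar strain (called mice in part of the labels) were kept for 4 weeks on a purified diet that held iron or lacked it, after which liver and kidney were taken. Each group is 1 array, made from RNA pooled from 3 cultures for FAO cells and from 6 animals for each tissue and diet. With 1 array per group there is no replicate check and no test: genes are called by size alone, at least 2-fold higher or lower. Differences are treated minus control on the log2 scale, given with ± a standard error from the spread between repeated spots, which covers technical spot noise only. That spread is pooled over probes of similar signal on an array and is not the gene's own. It can understate the error of genes with spots in noisy blocks.

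Of 30367 gene probes, the share well above background was 40.2% on the iron-sufficient liver array, 47.7% on the iron-free liver array, 37.7% and 40.5% on the matching kidney arrays, 48.5% on the untreated and 48.8% on the deferoxamine FAO array. No gene spot was saturated. The tissue labels held: albumin (Alb) had a signal of 51802 in control liver and 20.3 in control kidney, and uromodulin (Umod), a kidney tubule protein, had 7.60 in control liver and 138940 in control kidney. Repeated spots of a probe departed from each other over parts of some arrays. Of 264 blocks of 16 by 16 spots per array, the number of noisy blocks was 40 on the control liver array, 18 on the control kidney array, 13 on the deferoxamine array and 6, 4 and 1 on the iron-free kidney, untreated FAO and iron-free liver arrays. The deferoxamine array had a dim patch at rows 129 to 224 and columns 65 to 96, where spots departed by a block median as low as -5.30 from their probe's median, and the control kidney array had 4 dim blocks, as low as -5.79.

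**Figure D1:**
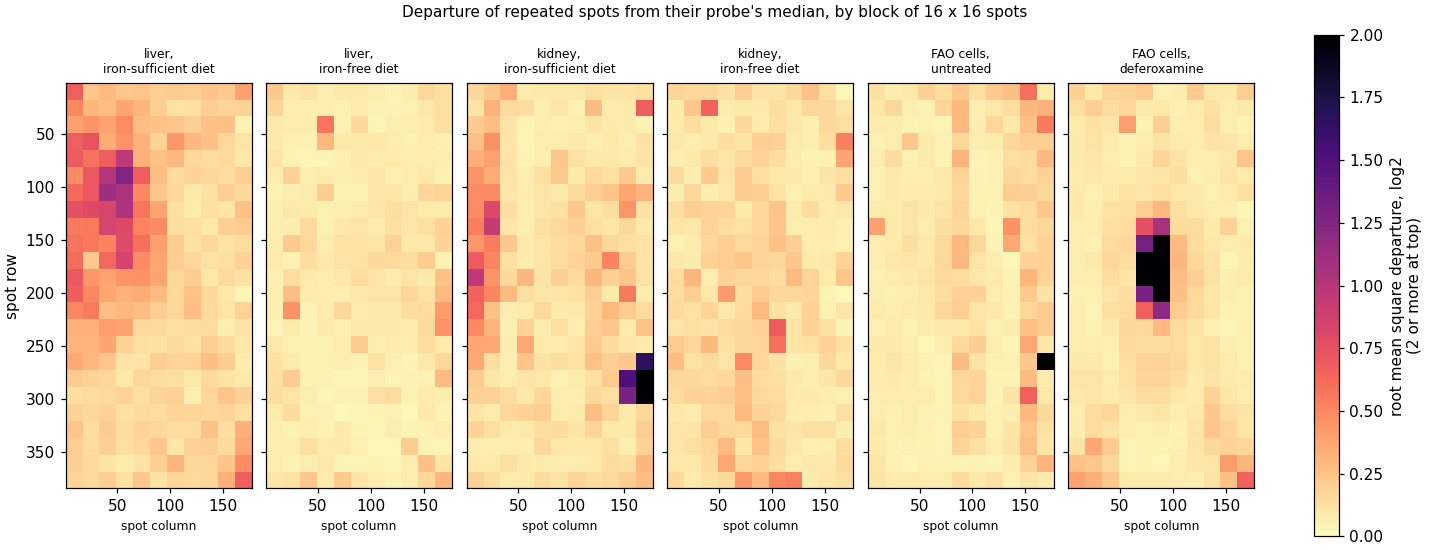
Root mean square departure (log2 units, colour) of repeated spots from their probe's median in blocks of 16 by 16 spots, drawn at each block's spot row and column for the 6 arrays. The dark patch near the centre of the deferoxamine array lies at rows 129 to 224. The control kidney array has a patch at its right edge, but its 4 dim blocks range over columns 1 to 164. The control liver array has 40 noisy blocks, most of them at the upper left.

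The FAO comparison addressed which genes respond to iron chelation in liver cells. Deferoxamine-treated cells had more RNA of hypoxia-inducible factor targets, glycolytic enzymes, immediate early genes, p53 targets and acute phase proteins than untreated cells, and less RNA of xenobiotic-metabolising enzymes. Atf3, a stress-induced transcription factor, was 57.9-fold higher (log2 5.86 ± 0.40). Transferrin receptor (Tfrc, gene ID 64678), which takes iron into cells, was 2.87-fold higher (1.52 ± 0.16), and 2.08 by its other probe. The ferritin chains Fth1 and Ftl1, which store iron, and the iron exporter ferroportin (Slc40a1) stayed within 2-fold at 0.21 ± 0.15, 0.13 ± 0.15 and 0.27 ± 0.28, values whose sign turned under some of the alternatives. Over 10706 measured genes, 435 were at least 2-fold higher and 698 at least 2-fold lower.

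Among targets of hypoxia-inducible factor, the transcription factor that low oxygen or low iron stabilises, 20 of 29 measured genes were at least 2-fold higher, with a median of 1.31. That median lay at percentile 100 of 10000 random lists of matched signal, as a description of these arrays. Angptl4, a lipoprotein lipase inhibitor, was 9.02-fold higher (3.17 ± 0.46). The glucose transporter Slc2a1 was 3.74-fold higher, carbonic anhydrase Car9 5.40-fold and adrenomedullin (Adm) 5.20-fold. Of 17 glycolysis genes, 5 were higher and 2 lower (median 0.72, percentile 100): Eno2 rose 10.4-fold (3.38 ± 0.33) and Aldoc 2.90-fold (1.54 ± 0.89, with 0.48 by its other probe).

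Immediate early genes, transcribed within minutes of a stimulus, were higher in 14 of 17 cases (median 1.58, percentile 100), among them Jun at 3.41 ± 0.86, Egr1 at 2.97 and Nr4a1 at 2.93. In the list of p53 targets and apoptosis genes, 12 of 29 were higher and 0 lower (median 0.76, percentile 100), with Btg2 at 2.82 ± 0.18, Tp53inp1 at 1.73 ± 0.63 and Mdm2 at 1.42. Cdkn1a, the cell-cycle inhibitor of that list, was at 0.28. Acute phase and inflammation genes were higher in 11 of 24 cases (median 0.91, percentile 100): the chemokine Cxcl1 rose 5.97-fold (2.58 ± 0.21), Cxcl2 at least 5.55-fold, lipocalin 2 (Lcn2), which binds iron-carrying siderophores, 5.43-fold (2.44 ± 1.13), and the fibrinogen chain Fga 3.38-fold. Plat, tissue plasminogen activator, was 10.4-fold higher (3.38 ± 0.19), Reg3b, a secreted lectin, 9.86-fold (3.30 ± 0.19) and Txk, a tyrosine kinase, 18.3-fold (4.19 ± 0.86). Znrf2 was 17.5-fold higher by a probe with 1 spot, which lay in a noisy block, and its other probe gave -0.75. Rsad2, an interferon-induced antiviral protein, was at least 32.4-fold higher. For Gpc6 and Krtap3-3, at least 120-fold and 32.8-fold higher, the only spot lay in a noisy block.

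Xenobiotic-metabolising enzymes were lower in 8 of 24 cases and higher in 0 (median -0.58, percentile 0): Cyp2a1 was at least 7.92-fold lower, Gsta2, a glutathione transferase, 6.36-fold (-2.67 ± 0.19) and Cyp2e1 3.49-fold (-1.80 ± 0.12). Gsta2 had a deferoxamine spot in a noisy block and was at -2.17 without it. Of 9 bile acid genes 3 were lower (median -0.65, percentile 0.14), including Baat, which conjugates bile acids, at -1.85 ± 0.25 and the transporter Slco1a4, at least 3.20-fold lower. Hepatocyte markers had a median of -0.42 (percentile 0), with 5 of 22 lower and 1 higher. Aldh1a7, an aldehyde dehydrogenase, was 11.1-fold lower (-3.47 ± 0.43), and the fatty acid transporter Cd36 at least 4.27-fold. Hmox1, which breaks down heme, was 3.70-fold higher (1.89 ± 0.08) while the heme list as a whole had a median of -0.32 (percentile 0.15). Respiratory chain genes lay close together at a median of -0.18 (percentile 0.015), with 4 of 53 lower and none of these 4 lower once spots in noisy blocks were left out. Hepcidin (Hamp, gene ID 84604), the liver hormone that lowers iron export, was at 0.73 ± 0.14 and Rgn (gene ID 25106), whose product is the senescence marker protein 30, at -0.74 ± 0.12, both within 2-fold.

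The largest decreases came mostly from noisy blocks of the deferoxamine array. Of the 8 largest among genes above background on both arrays (Slc12a9, Stk24, Psmb4, Grhpr, Uba2, Dnaja1, Ewsr1 and Aldh1a7), 7 had a spot in a noisy block. Without such spots Aldh1a7 stayed at least 2-fold lower, Psmb4 (0.14), Dnaja1 (-0.08), Ewsr1 (-0.31) and Atp5mc3 (-0.06, among the 3 largest bounds) did not, and Slc12a9, Stk24, Grhpr, Uba2 and the bounds Surf4 and Scaf11 had no spot left. By other probes Grhpr was at -0.07 and Stk24 at -0.53 and 0.69. Without spots in noisy blocks the count was 436 higher and 390 lower genes of 10525. In simulated pairs 7.45% of unchanged genes passed the size rule in a step of 10155 genes, or 4.61% in a step of 10137 with noisy blocks left out. The first share draws noise at a pooled spread that includes the dim patch, so it can overstate the noise of genes outside the patch. Neither share covers the 147 higher calls made as bounds, since only probes well above background on the control array were simulated.

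**Figure D2:**
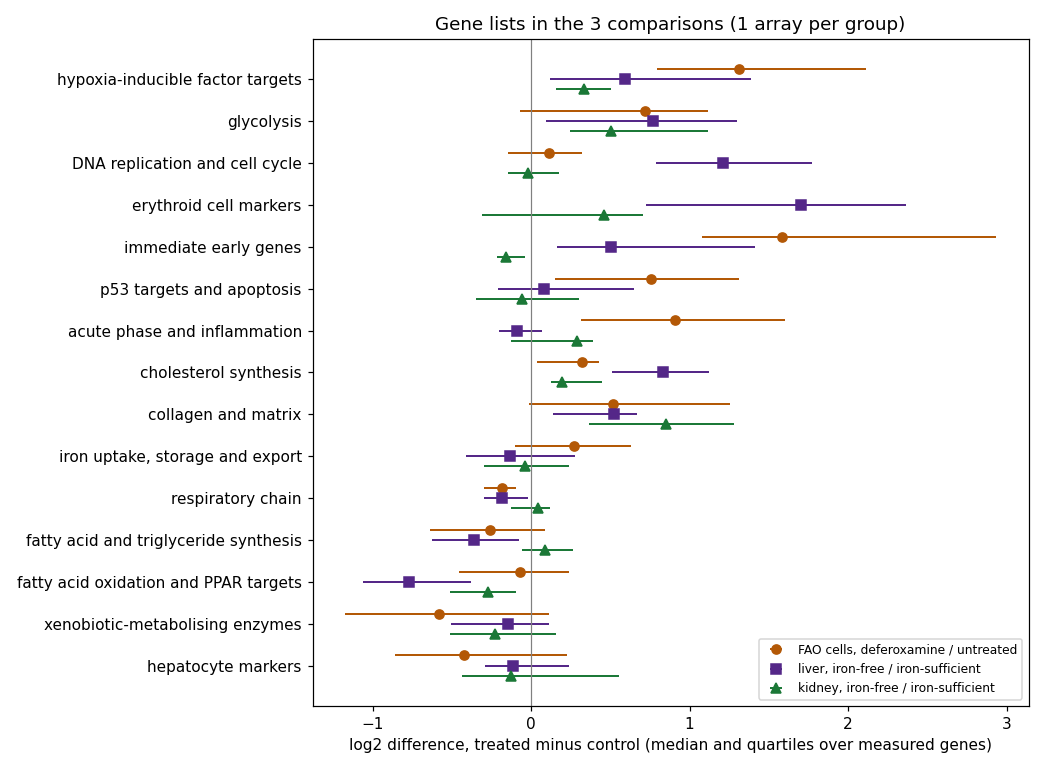
Median log2 difference (points) with quartiles (bars) over the measured genes of 15 gene lists in FAO cells, liver and kidney, treated minus control, 1 array per group. Hypoxia-inducible factor targets had medians of 1.31, 0.59 and 0.33, and cell-cycle genes stood at 1.21 in liver against 0.11 in FAO cells and -0.02 in kidney. Under scaling to the median of detected probes, negative medians as low as -0.55 in liver and -0.20 in kidney turned positive. Both of these belong to gluconeogenesis and glycogen, a list not drawn here. Fatty acid and triglyceride synthesis in liver, which is drawn, turned from -0.36 to 0.22.

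The liver comparison addressed which genes respond to 4 weeks without dietary iron. Iron-free liver had far less hepcidin RNA, more transferrin receptor RNA, more RNA of cell-cycle, erythroid, cholesterol synthesis and glycolysis genes, and less RNA of fatty acid oxidation genes than control liver. Hamp was 829-fold lower (-9.70 ± 0.19), with a signal of 69.1 against 44253, and Tfrc 13.1-fold higher (3.71 ± 0.26; 3.01 by its other probe). Ferritin stayed within 2-fold (Fth1 -0.09 ± 0.27, Ftl1 -0.32 ± 0.27, both positive under scaling to the median of detected probes), and Slc40a1 was at 0.99 ± 0.26 by its brightest probe and -0.13 by the other, with both control spots of the brightest probe in noisy blocks. Rgn was 2.80-fold higher (1.48 ± 0.13, and 1.14 without noisy blocks). Of 10175 measured genes 664 were at least 2-fold higher, 381 of them as bounds against a control below background, and 308 at least 2-fold lower.

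DNA replication and cell-cycle genes were higher in 30 of 51 cases and lower in 1 (median 1.21, percentile 100). Cdk1, the mitotic kinase, was 10.3-fold higher (3.36 ± 0.20), and Rrm2, a subunit of ribonucleotide reductase, 9.28-fold (3.21 ± 0.28) by 1 probe and 0.10 by the other. Mki67, a proliferation marker, was at least 7.85-fold higher, while cyclin D1 (Ccnd1) was 3.32-fold lower. Erythroid cell markers moved with them: 7 of 11 were higher and 0 lower (median 1.71, percentile 100), with Rhd, a blood group protein, at 3.06 ± 0.58, Ahsp, which stabilises alpha-globin, at 2.76 ± 0.27 and Alas2, the erythroid enzyme that starts heme synthesis, at 1.80 ± 0.27. Leukocyte and macrophage markers had 4 of 20 higher (median 0.18, percentile 95.4), with S100a8 at least 2.90-fold higher, and hepatocyte markers had 4 of 30 higher and 1 lower (median -0.12, percentile 45.5, a sign that scaling to the median of detected probes turned).

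Hypoxia-inducible factor targets were higher in 10 of 26 cases and lower in 1 (median 0.59, percentile 100): Egln3, an oxygen-sensing hydroxylase, was at least 4.43-fold higher, Kdm3a, a histone demethylase, at least 3.66-fold and Slc2a1 2.66-fold, whereas Angptl4 was 2.26-fold lower. Without noisy blocks 7 of 25 were higher and 0 lower (median 0.56), so that Angptl4 was no longer called. Of 19 glycolysis genes 8 were higher and 1 lower (median 0.77, percentile 100), with Aldoc at least 7.35-fold higher by its brightest probe and 0.15 by the other, Eno2 at least 3.76-fold by its brightest probe and 0.48 by the other, and Pfkl, the liver phosphofructokinase, 2.43-fold (1.28 ± 0.31). The liver pyruvate kinase Pklr was 2.57-fold lower.

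Cholesterol synthesis genes were higher in 8 of 24 cases and lower in 0 (median 0.83, percentile 100), led by squalene epoxidase (Sqle) at 2.59 ± 0.27. Fatty acid oxidation genes and other PPAR targets were lower in 9 of 31 cases and higher in 0 (median -0.77, percentile 0, and -0.18 under scaling to the median of detected probes): Fgf21, a fasting hormone, was at -1.86 ± 0.20, Pex11a at -1.72 ± 0.36 and Cpt1a, which admits fatty acids to mitochondria, at -1.71. Stearoyl-CoA desaturases stood among the largest decreases, with Scd 5.83-fold lower (-2.54 ± 0.27), Scd4 9.02-fold (-3.17 ± 0.27) and Scd3 6.66-fold (-2.73 ± 0.40). Fatty acid and triglyceride synthesis as a list had 2 of 20 lower (median -0.36, percentile 0.21), a sign that turned to 0.22 under scaling to the median of detected probes.

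Other large differences in liver were Akr1b8, an aldo-keto reductase, 15.7-fold higher (3.98 ± 0.49), Gstm3, a glutathione transferase, 7.76-fold higher (2.96 ± 0.49), Cyp1a2, a drug-metabolising cytochrome, 6.32-fold higher (2.66 ± 0.25) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at least 6.49-fold higher (2.70, and 1.96 without noisy blocks). Nr4a1 was at least 12.7-fold higher and Gdf15, a stress hormone, at least 6.83-fold. Lower were Hsd17b2, a steroid dehydrogenase (-2.98 ± 0.27), Aldh1a1, a retinal dehydrogenase (-2.64 ± 0.27), the clock-controlled factor Dbp (-2.56 ± 0.25) and Stac3 (-2.35 ± 0.38). The largest bounds were Alox15, Lypd8 and Cdyl, at least 60.1-fold, 27.0-fold and 23.5-fold higher, and Ntrk3, Tmem131l and Spata31d1, at least 54.4-fold, 36.5-fold and 27.4-fold lower; of these 6 only Alox15 was read from more than 1 spot per array, at 5.91 with all spots and 4.42 without noisy blocks, and Lypd8 then had no value left. The counts depended on scaling: set to the median of detected probes, values shifted by a median of 0.58 and 2122 genes were higher and 79 lower, in place of 664 and 308. That median is taken over each array's own detected probes, 40.2% of probes on control and 47.7% on iron-free liver. Without noisy blocks 522 were higher and 289 lower. Among genes left unchanged in simulated pairs, 3.01% passed the size rule in a step of 8650 genes. The simulation measured only probes well above background on the control array. That share therefore has no counterpart for the 381 higher calls made as bounds.

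The kidney comparison asked the same question in a second tissue. Iron-free kidney had more RNA of transferrin receptor, Ahsp, collagen and matrix genes and several glycolytic genes, and a slightly lower median over fatty acid oxidation genes. Tfrc was 7.97-fold higher (2.99 ± 0.20; 0.90 by its other probe) and Ahsp 11.2-fold (3.49 ± 0.55; 2.95 by its other probe). Ferritin and ferroportin stayed within 2-fold (Fth1 0.13 ± 0.20, whose sign turned under 1 alternative, Ftl1 -0.32 ± 0.20, Slc40a1 0.26 ± 0.26), as did Rgn at 0.49 ± 0.12, and Hamp was not well above background on either kidney array. Of 8958 measured genes 281 were at least 2-fold higher and 116 lower.

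Collagen and matrix genes were higher in 7 of 16 cases and lower in 0 (median 0.85, percentile 100), among them Loxl2, a collagen cross-linking enzyme, at least 4.09-fold, Fn1 (fibronectin) 2.67-fold, Col3a1 2.47-fold and Col1a2 2.42-fold (1.27 ± 0.18). Markers of stellate cells and fibroblasts, which share 3 collagens with that list, had 2 of 10 higher and a median of 0.81 (percentile 100). The list of hypoxia-inducible factor targets shares P4ha1, P4ha2 and Plod2 with collagen and matrix, and Hk2, Pgk1 and Ldha with glycolysis. Their medians are therefore not independent. Hypoxia-inducible factor targets were higher in 4 of 25 cases and lower in 2 (median 0.33, percentile 100), with P4ha1, a collagen prolyl hydroxylase, at 1.61 ± 0.43 and Angptl4 at -1.66 ± 0.24. Glycolysis had 5 of 18 higher and 0 lower (median 0.50, percentile 100), with Aldoc at least 4.04-fold and Pfkl 2.36-fold higher (1.24 ± 0.25). Pfkp, at least 15.9-fold higher in all spots, was at 0.90 without the noisy block that held 1 of its control spots. Cell-cycle genes had 0 of 29 called (median -0.02), and erythroid markers 2 of 10 higher, Ahsp and Hbb (1.18 ± 0.20, and -0.13 by its other probe), with a median of 0.46 (percentile 99.95).

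Fatty acid oxidation genes had a median of -0.27 (percentile 0), with 1 of 30 lower. The size of that median depends on scaling, since the median of detected probes shifted kidney values by a median of 0.20. Kidney tubule and glomerulus markers had 0 of 31 called (median -0.15, percentile 0.96, and 0.05 under scaling to the median of detected probes). Also higher were Tyro3, a receptor tyrosine kinase, 20.6-fold (4.37 ± 0.20), Rarres2 (chemerin) 11.2-fold (3.49 ± 0.22), the lactate transporter Slc16a3 5.39-fold (2.43 ± 0.40), ceruloplasmin (Cp), a copper enzyme that oxidises iron, 2.63-fold (1.40 ± 0.31) and Alas1 2.09-fold (1.06 ± 0.27). Lower were Tmem65 (-4.98 ± 0.94) and Foxk1 (-3.10 ± 0.55), each by 1 spot, Gp2 (-1.55 ± 0.24), Nr2f2 (-1.54 ± 0.22), Fbxw11 (-1.15 ± 0.33, by 1 spot), Nt5c3a (-1.15 ± 0.24) and Dbp (-1.11 ± 0.25). The largest bounds, H2bu1, Ush1g and Map3k5 higher and Spink13, Shox1 and Rcor3 lower, were each read from 1 spot per array. Rpl13a, 20.6-fold higher in all spots, was at 0.28 with its noisy control spot left out, Ndufb6, at least 25.2-fold higher, was at -0.03, and Srbd1 and H2bu1 had no spot left. Without noisy blocks 220 genes were higher and 116 lower. Among genes left unchanged in simulated pairs, 2.60% passed the size rule in a step of 8251 genes. As in liver, that share has no counterpart for higher calls made as bounds, here 168 of the 281.

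**Figure D3:**
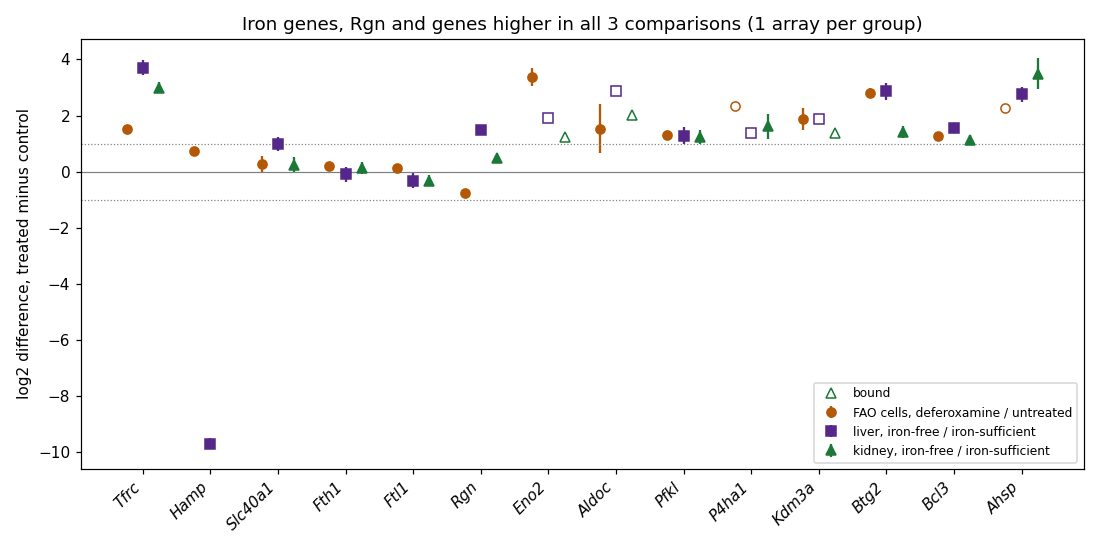
Log2 difference, treated minus control, of the iron genes, Rgn and 8 genes higher in all 3 comparisons, with bars of ± the spot standard error; open symbols are bounds, dotted lines mark 2-fold, and Hamp has no kidney value. Tfrc lies at 1.52, 3.71 and 2.99 in FAO cells, liver and kidney, and Hamp at -9.70 in liver.

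Across the 3 comparisons, 12 of the 7412 genes measured in all were at least 2-fold higher in each and 0 were lower in each, against 0.181 and 0.0408 for independent lists of the same sizes. The 12 were Tfrc, the glycolytic genes Eno2, Aldoc and Pfkl, the collagen-modifying enzymes P4ha1, Plod1 and Loxl2, the demethylase Kdm3a, Btg2, Bcl3, Ahsp and LOC498829. Only 5, Tfrc, Pfkl, Plod1, Btg2 and Bcl3, were well above background on both arrays of every comparison. The others rest on a bound in at least 1 comparison, as Ahsp does in FAO cells. Aldoc, Kdm3a and LOC498829 were read from 1 spot per array. By other probes Aldoc was at 0.48 in FAO cells and 0.15 in liver, and Eno2 at 0.48 in liver. Bcl3, a nuclear inhibitor of the kappa B family, was 2.45-fold, 2.92-fold and 2.18-fold higher in FAO cells, liver and kidney, and Btg2, an antiproliferative p53 target, 7.04-fold, 7.28-fold and 2.66-fold. Leaving out spots in noisy blocks gave 9 such genes, since Plod1 was then at 0.92 in liver and Loxl2 and Kdm3a had no liver value.

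By pairs, FAO cells and liver shared 64 higher genes, where independent lists would share 15.6, and 25 lower genes (11.8). FAO cells and kidney shared 22 higher (4.33) and 6 lower (2.76), and liver and kidney 55 higher (10.3) and 4 lower (1.14). Some opposite overlaps also lay above independence: 12 genes were higher in FAO cells and lower in liver (6.48), 6 higher in FAO cells and lower in kidney (1.498) and 8 higher in liver and lower in kidney (2.99). The reverse overlaps were 28 (28.5), 4 (7.98) and 2 (3.93). No array is shared between comparisons, but liver and kidney could come from the same animals, which the labels leave open. Across genes, which are not independent replicates, the differences correlated with Pearson's r of 0.149, 0.0863 and 0.214 for these pairs (Spearman's rho 0.176, 0.109 and 0.210). Leaving out noisy blocks lowered the liver and kidney overlap to 30 higher (5.45) and 2 lower genes (0.735).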

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

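All tests in this part were chosen after the results were seen, though 4 of the 5 other scalings used below were fixed beforehand.

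Genes called in opposite directions in liver and kidney under the same diet change stood out, 8 higher in liver and lower in kidney and 2 the other way, and their difference between tissues was not tested. The naming rule takes 6 of them. Atf3 was at 1.90 in liver and -1.19 in kidney, both well above background on each array with 2 spots. The other 5 named are bounds on the log2 scale: Cdyl at 4.56 and -2.80, Col4a6 at 2.57 and -3.14, Cxcl13 at 1.18 and -1.94, Cfap251 at -2.64 and 1.79 and Spetex-2A at -1.62 and 1.18. Of these, Cdyl, Col4a6 and Cfap251 were read from 1 spot per array, and in kidney the only control spot of Cdyl and of Cfap251 lay in a noisy block, so that neither has a kidney value without such blocks. Probes that carry no gene ID, which no comparison used, also held signals that differed from the control array: 411 of 2934 measured in FAO cells, 379 of 2604 in liver and 286 of 2281 in kidney were at least 2-fold different.

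More genes were lower than higher on the deferoxamine array. The dim and noisy blocks of that array could account for this excess: 49.1% of the genes called lower had a spot in such a block, against 8.62% of uncalled genes and 5.75% of genes called higher. They do not account for all lower calls, since 355 genes called lower had no spot there, beside 410 called higher, and these include the drug-metabolising Cyp2a1 and the bile acid gene Baat. Spot noise and iron chelation both remain open for those, untested with 1 array per group. With noisy blocks left out, 4.14% of measured genes were called higher and 3.71% lower. In simulated pairs 4.61% of unchanged genes then passed the size rule, both directions counted. That simulation measured only probes well above background on the control array, so higher calls against a dim control lie outside it.

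Cell-cycle genes were higher in iron-free liver. Noisy blocks of the control array do not account for it, because the list's median was 1.32 with 30 of 50 genes called when noisy blocks were left out, and scaling does not remove it, since the lowest median among 5 other scalings was 1.15. Blood left in the tissue that carries cell-cycle and erythroid RNA cannot be told apart from a change in the liver: in kidney the 17 measured genes had a median of 0.11 (quartiles -0.02 to 0.32), below the 0.53 that the erythroid rise there predicts, but the prediction from the lowest erythroid ratio, 0.23, lies within those quartiles. By the median erythroid ratio of 0.36 behind that 0.53, 16 of the 17 lay below their expected value, and 0 were at least 2-fold higher where 6 were expected. All 17 expectations share that ratio, which ranged from 0.14 to 0.47 over 6 erythroid genes, so these counts do not decide the question. Dividing erythroid precursors in the liver are a candidate source, as erythroid markers had a median of 1.71 with 7 of 11 called higher, but these values do not separate them from other dividing cells.

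Among clock genes, 2 were higher and 3 lower of 9 in liver, and in kidney only Dbp, 1 of 8, passed the size rule. Dbp was at -2.56 in liver and -1.11 in kidney, Tef at -1.03 and -0.58, Bmal1 at 1.01 and 0.60 and Cry1 at 1.24 and 0.82, and 8 of the 8 clock genes measured in both tissues had the same sign in both. Such a pattern could arise if the diet groups were sampled or had fed at different hours, which could also touch cholesterol and fatty acid genes. It cannot be told apart from an effect of the diet, because each diet is 1 pool per tissue and no hour is given in the labels used here. In FAO cells, which have no feeding time, 7 of those 8 were measured and 7 of these 7 shared the sign of liver.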

How the results depend on the processing

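Alternatives marked below as added were chosen after the data were seen, and all others were fixed before. The main values were 1133 genes called in FAO cells, 972 in liver and 397 in kidney, 12 in all 3 comparisons, and overlaps of 89 (FAO cells and liver), 28 (FAO cells and kidney) and 59 (liver and kidney). Values below follow this order. The cause of each change was not tested, except where the construction of the rule sets it, as with stricter or looser size and detection rules.

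Size rules moved every count. At 1.5-fold they were 2393, 2444, 1097, 47, 346, 123 and 235, and at 3-fold 525, 328, 163, 1, 19, 7 and 14. Asking for 2-fold and over 3 spot standard errors gave 528, 554, 209, 5, 53, 14 and 30. These errors came from a probe's own spots where it had 2 or more, unlike the pooled ones given with ±.

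Detection rules moved them too. Signal well above background on both arrays gave 671, 507, 157, 5, 47, 13 and 25, and a brighter array at or above its median of detected probes 428, 390, 130, 4, 41, 8 and 24. No background filter gave 2856, 3209, 1614, 28, 308, 147 and 224. In kidney, the median of acute phase genes turned to -0.13 with the brighter array rule and to -0.18 without a background filter, which also turned the circadian clock to -0.35 and endothelial markers to -0.00747. Signal over background therefore limits these counts, since bounds make up 381 of the 664 higher calls in liver.

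Scaling to the median of detected probes gave 2201 calls in liver (2122 higher and 79 lower, against 664 and 308) and 487 in kidney (405 and 82, against 281 and 116), with overlaps of 137 for FAO cells and liver and 137 for liver and kidney. It shifted values by a median of 0.58 in liver and 0.20 in kidney. By construction it compares medians over unequal probe sets, each array's own detected probes. The detected share was 40.2% against 47.7% in liver and 37.7% against 40.5% in kidney, control first. How far this accounts for the shift was not tested. Under it the medians of fatty acid and triglyceride synthesis (0.22) and gluconeogenesis and glycogen (0.0350) in liver and of kidney tubule and glomerulus markers in kidney (0.0472) turned positive, counting only lists whose main median lay in the outer tails of the random lists. Smaller negative medians in liver and kidney turned as well. None of the other scalings turned the medians of these named lists. Quantile normalization, loess centring, the authors' table, outlier spots kept, the mean over probes and the 75th percentile over all probes (added) moved no count by over 1.5 times. The authors' table is itself scaled to the 75th percentile, so it and the last of these are nearly the same setting.

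Normexp on the median signal (added) gave 545 calls in liver, 264 in kidney, 5 in all 3 comparisons and overlaps of 48, 17 and 31, and shifted liver values by a median of -0.14. Normexp on the mean signal, fixed beforehand, was not run because the files used here hold no mean signal column.

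Leaving out spots in noisy blocks (added) changed the liver and kidney overlap to 32. FAO calls became 436 higher and 390 lower, against 435 and 698. Insig1 (1.66) and Psmb4 (0.14) in FAO cells, Lyz2 in liver (-0.17) and Ndufb6 in kidney (-0.0292) changed sign. Keeping only probes with 2 or more spots that do not overlap between arrays (added) gave 594, 546 and 142 calls and overlaps of 16 for FAO cells and kidney and 29 for liver and kidney.

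Reversed means a change of sign in a called gene or in a list in those tails, so sign changes of uncalled genes count as moved or the same. Over all alternatives, 138 of 1159 list medians moved and 7 reversed, and 252 of 2359 values of named genes moved and 4 reversed. These were uneven: normexp moved 100 named genes and left 97 the same, and scaling to the median of detected probes moved 60 named genes and 58 list medians, leaving 137 and 37 the same. No paired analysis was possible because each group is 1 array.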

Other observations

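In iron-free liver 6 of 32 stress response genes were higher and 1 lower (median 0.07, percentile 92.8), and 3 of the higher ones, picked after their values were seen, encode serine synthesis and folate enzymes. Phgdh, which starts serine synthesis, was 6.42-fold higher (2.68 ± 0.29), Psat1 4.08-fold (2.03 ± 0.31) and the mitochondrial folate enzyme Mthfd2 3.93-fold, while Atf4, Ddit3 and Trib3 of the same list were at -0.18, 0.02 and -0.09. With noisy blocks left out, Psat1 was at 1.13. In FAO cells Phgdh, Psat1 and Mthfd2 were at -0.51, -0.05 and 0.17, and there Trib3, Chac1 and Cebpb were at 1.38, 1.34 and 1.54. Bile acid genes in liver went different ways, with Cyp7a1 higher, the repressor Nr0b2 at -1.37 ± 0.27 and the bile acid receptor Nr1h4 at -1.22. These were the only calls among 16 measured (median -0.24, percentile 7.69). Targets of the transcription factor NRF2 also went different ways, with 3 of 25 higher and 3 lower (median -0.02, percentile 69.2). Akr1b8, Gstp1 (1.66 ± 0.26) and Nqo1 (at least 2.61-fold) were higher. Aldh1a1, Ephx1 (-1.30) and Me1 (-1.11 ± 0.13, and -0.94 without noisy blocks) were lower.

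In FAO cells Plin2, which coats lipid droplets, was 3.17-fold higher, Acot2, a mitochondrial thioesterase, 3.48-fold (1.80 ± 0.18) and Cpt1b 2.66-fold, against -0.84, -1.08 and no measured value in iron-free liver. Alas1, the enzyme that starts heme synthesis in most cells, was 2.41-fold higher in FAO cells and 2.09-fold higher in kidney, and at -0.80 in liver. Fbxl5, whose protein senses iron and degrades iron regulatory protein 2, was at -1.08 in liver, -0.95 in kidney and -0.27 in FAO cells. In liver, the sinusoidal endothelial genes Lyve1 and Stab2 were 2.04-fold and 2.02-fold higher and the pericyte gene Rgs5 2.93-fold, the only calls among 13 endothelial markers (median 0.22, percentile 90.5) and 11 stellate cell and fibroblast markers (median 0.18, percentile 89.8).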
